A study of Homo sapiens with 3 samples.

How the data were processed

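Total RNA from T47D cells was labelled with biotin and hybridised to Affymetrix HG-U133 Plus 2 arrays, per the labels' protocols. There were 3 arrays, 1 each for vehicle, estradiol and ERα17p, all at 3 h, and each array was put in its group by its label. The series title speaks of a time course, and other times are not analysed here. The deposited values were made with RMA, per the submitters' processing notes, and its version is not given in the sources used here. They were taken as log2 expression values because RMA gives log2 values and the deposited table names no other base. The deposited values lay around 0, with array medians of −0.0097 for vehicle, −0.0001 for estradiol and −0.0029 for ERα17p, so each probe set had been set relative to a baseline. That baseline was neither the median nor the mean of these 3 arrays: 0.496% of probe sets had a value within 0.0001 of 0 on any array, and the 3 values of 0.024% summed to within 0.0001 of 0. The centring step, its software, its baseline and the log base are not given in the sources used here. Differences between arrays do not depend on the baseline if 1 baseline served all 3, which could not be checked. The direction of the differences was taken from the labels.

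The arrays held 54675 probe sets, 62 of them controls. The platform annotation gave 41091 probe sets 1 gene and 1801 several genes, and 11721 were without a gene name in it. Of the probe sets with 1 gene, 41037 matched a current human gene record by their gene number, and 0 of their symbols needed an update. Probe sets with several genes or none were left out of all gene results. A gene's difference was the mean over all of its probe sets, for 19775 genes, of which 9252 had 1 probe set and 10523 had more. The SD over these probe sets is the spread given. The number of arrays limits the precision, and signal over background is unknown because no absolute level was kept. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

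The comparisons were estradiol minus vehicle, ERα17p minus vehicle and ERα17p minus estradiol. With 1 array per group no significance test was run. Genes were counted by size, at a difference of at least 1 on the log2 scale (2-fold). For each of 25 gene lists the median difference was set among the medians of 10000 random lists of the same size, and a list was called outside when it lay beyond the central 95%. The random genes were matched on the number of probe sets per gene, in 5 classes. Because listed genes are mostly well studied and expressed, a second set of random lists was drawn from the 694 genes of all lists, an addition made after the data were seen. In all 75 list medians were computed, the results of 1 list are not reported here, and 5% of unrelated lists would lie outside a single range. The correlation of the differences from the shared vehicle was set beside the value from simulated unchanged arrays of equal noise and, as an addition made after the data were seen, beside 100 shuffles of each array's gene values across genes. The SD of these values over genes was 0.371 for vehicle, 0.130 for estradiol and 0.139 for ERα17p. Agreement of probe sets was measured on a randomly drawn pair of sets per gene.

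Named genes followed a fixed rule. For each comparison with the vehicle these were the 12 genes with the largest positive and the 12 with the largest negative difference, of at least 1.5-fold, and for ERα17p minus estradiol the 6 largest each way. Up to 4 members of each list with the largest absolute difference could be named per comparison. ESR1, ESR2, GPER1, PGR, TFF1, GREB1, MYC and CCND1 were always given. The lists, the rule, the comparisons and the thresholds were fixed before the data were examined.

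The design called for absolute levels, and these values have none. The planned floor at the median level, the brightest probe set as the value of a gene and random lists matched on expression could therefore not be used. In their place stood no floor, the mean of a gene's probe sets and matching on the number of probe sets. The first pair of these had been listed as alternatives. The floor at the 75th percentile, the pseudocount of 32 on the linear scale and cyclic loess normalization could not be run. Alternatives that were run were other size thresholds, differences centred on their median over genes, probe sets open to cross-hybridisation left out (those whose identifier ends in _x_at or _s_at), probe sets in place of genes, the mean of list members and unmatched random lists. The median of a gene's probe sets, genes with more than 1 probe set that all pass the threshold, and the vehicle array left out were added after the data were seen. Leaving out the probe sets open to cross-hybridisation also removed every gene with no other probe set, leaving 17098 genes. List medians without those sets can therefore cover fewer members, and a change in them can come from the membership.

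The gene computations were tested on simulated data of 19775 genes with noise of SD 0.167 and 50 genes at each size for estradiol minus vehicle. Genes moved by 0.5 on the log2 scale were called 2-fold in 0%, by 1.5 in 98%, and by 2 and by 3 in 100%, and 0 of 19575 unmoved genes were called. Of 100 unmoved lists of 30 genes, 3 fell outside the central 95%, and a list moved by 0.3 was at percentile 100. That noise was taken from the difference between the treated arrays, was given to all 3 simulated arrays and is no estimate of the spread between cultures. The real vehicle array had a wider spread, with an SD of 0.434 over probe sets. The 0 calls among unmoved genes therefore do not carry over to the comparisons with vehicle.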

Results

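Gene expression was measured in T47D cells, a human breast cancer line that carries estrogen receptor α and the progesterone receptor, on 3 Affymetrix HG-U133 Plus 2 arrays. After 4 h in medium with 10% hormone-depleted serum, the cells were given ethanol vehicle at 0.1%, estradiol at 1 µM or ERα17p at 1 µM, and RNA was taken 3 h later. An ethanol share was found for the vehicle cells alone. Whether the treated cells received the same solvent could therefore not be checked. Estradiol is the main natural ligand of the receptor. ERα17p is a synthetic peptide copied from the stretch of the receptor that binds calmodulin. The comparisons ask which transcripts differed early after each agent, and where the hormone and the peptide differed from each other at the same molar dose. Each group had 1 array, so no difference had an error between cultures and no p-value was computed. An SD given below is over the n probe sets of a gene. It covers probe noise within these arrays together with any other difference between those probe sets. Differences are on what was taken as the log2 scale, since neither the log base nor the baseline of the deposited values was stated, and fold sizes hold only for that base.

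The vehicle array stood apart from both treated arrays in its spread and in several control probe sets. Its values had an SD of 0.434 over all probe sets other than controls, against 0.158 on the estradiol array and 0.166 on the ERα17p array. This spread is taken around the deposited baseline. It therefore holds the gene differences reported below and depends on how that unknown baseline was set. Relative to the baseline of each set, the 3′ less the 5′ probe set of ACTB was 0.52 on the vehicle array. This difference was −0.29 on the estradiol array and −0.17 on the ERα17p array. For GAPDH the same difference was 0.39, −0.10 and 0.01 on the vehicle, estradiol and ERα17p arrays. Since each probe set has its own baseline, only the change between arrays can be read, not a 3′ to 5′ ratio within an array. Control probe sets for 18S ribosomal RNA were higher by 1.87 ± 0.34 (SD, n = 3) on the estradiol array than on the vehicle array, and by 1.76 ± 0.39 on the ERα17p array. The poly-A spikes, bacterial transcripts added to the RNA before labelling, were higher by 0.70 ± 0.29 (SD, n = 24) and 0.45 ± 0.29. The hybridisation spikes differed by −0.15 ± 0.12 (SD, n = 18) and −0.17 ± 0.19. Between the ERα17p and estradiol arrays, the mean differences were −0.12 for 18S, −0.24 for the poly-A spikes and −0.02 for the hybridisation spikes.

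**Figure D1:**
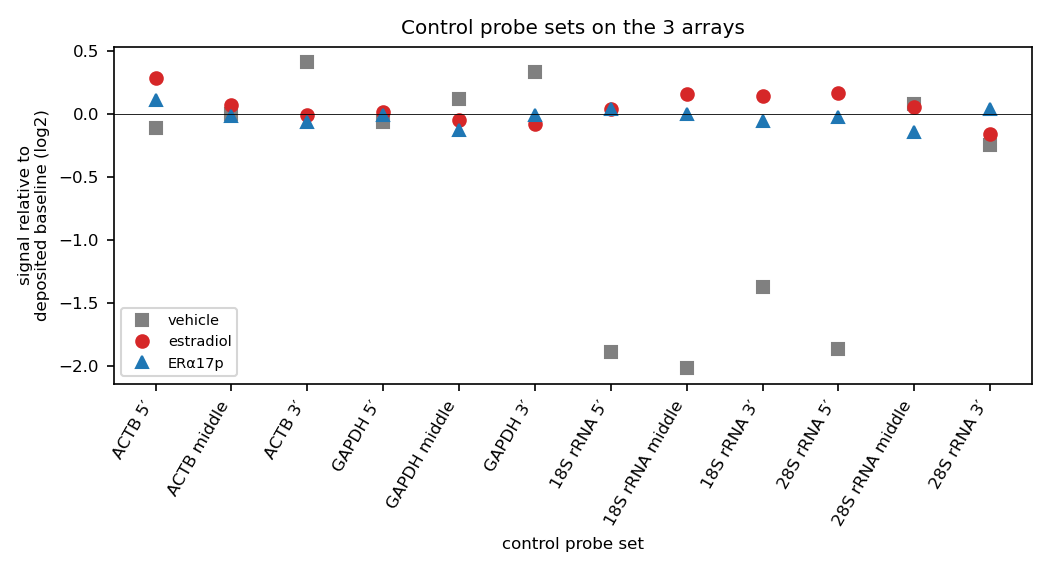
Signal of the control probe sets for ACTB, GAPDH and ribosomal RNA on each of the 3 arrays, on the log2 scale relative to the deposited baseline. Relative to the baseline of each set, the 3′ less 5′ difference is larger on the vehicle array (ACTB 0.52, GAPDH 0.39) than on both treated arrays. The vehicle array has lower signal than both treated arrays for all 18S sets.

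In the estradiol array, mitotic genes, histone genes and many known estrogen-induced genes were higher than in the vehicle array, while genes of the integrated stress response and NF-κB target genes were lower. MYC, a growth-promoting transcription factor, was higher by 2.07 (1 probe set), and PGR, the progesterone receptor, by 1.44 ± 0.28 (SD, n = 2). The spindle gene ASPM was higher by 2.17 ± 0.75 (SD, n = 3). CHAC1, which degrades glutathione, and DDIT3, a transcription factor of the stress response, were lower, at −3.71 and −2.92. The chemokine CCL20 stood at −2.73, and TFF1, a classical estrogen-induced gene, was also lower, at −2.19. Of 19775 genes, 310 were at least 2-fold higher and 323 at least 2-fold lower in the estradiol array.

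Among the estrogen-induced genes, 42 of 47 were measured. Their median difference was 0.34, above the central 95% of 10000 random lists (−0.13 to 0.10) and of lists drawn from all listed genes (−0.23 to 0.12). At least 1.5-fold higher were 13 members, at least 1.5-fold lower 5, and 28 lay above 0. Besides MYC and PGR, the zinc transporter SLC39A6 was higher by 1.89 ± 1.10 (SD, n = 4), whereas AMIGO2 stood at −1.53. GREB1, a cofactor of the receptor, differed by 0.94 ± 0.84 (SD, n = 3). The median was 0.16 over the 33 members left when probe sets open to cross-hybridisation were left out, still above its own random range (−0.13 to 0.12). CCND1, the gene of cyclin D1, stood at 0.33 ± 0.99 (SD, n = 2) and at −0.37 without those probe sets.

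The G2 to M cell cycle genes had a median of 0.62 over 34 members, of which 19 were at least 1.5-fold higher and 0 lower. CENPA, a centromere histone, was higher by 1.95, CDK1, the mitotic kinase, by 1.86 ± 1.05 (SD, n = 4), and NEK2 by 1.62 ± 1.83 (SD, n = 2). Of 16 listed histone genes 9 were measured, with a median of 0.54, and 4 were at least 1.5-fold higher, among them H2BC4 at 1.30 and H4C8 at 1.13 ± 0.57 (SD, n = 2). Heat shock genes had a median of 0.27 and a mean of 0.15 over 21 members, of which 2 were at least 1.5-fold higher and 0 lower. HSPA4L was higher by 1.41 ± 0.32 (SD, n = 2) and HSPH1 by 0.76 ± 0.40 (SD, n = 3). Without the probe sets open to cross-hybridisation, however, the list median was −0.08 over the 15 members left, inside its random range. Interferon response genes had a median of 0.13 and a mean of −0.05 over 37 members, with 6 at least 1.5-fold higher, such as IFIT1 at 1.55, and 9 lower, such as IRF1 at −2.50 ± 0.99 (SD, n = 2). That median was 0.02 over the 28 members left without the probe sets open to cross-hybridisation. With the median of a gene's probe sets it was 0.04, and both were inside the random range.

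Genes of the unfolded protein and amino acid stress responses had a median of −0.51 over 36 members, with 16 at least 1.5-fold lower and 5 higher. Besides CHAC1 and DDIT3, SESN2 stood at −2.37 ± 0.46 (SD, n = 2) and DDIT4, an inhibitor of mTOR signalling, at −2.18. NF-κB and inflammatory genes had a median of −0.68 over 31 members, with 16 at least 1.5-fold lower and 0 higher. TNFAIP3, a feedback inhibitor of NF-κB, stood at −2.43 ± 0.39 (SD, n = 2), and TNF at −2.24. The median of this list was −0.39 over the 23 members left without the probe sets open to cross-hybridisation. Cholesterol and fatty acid synthesis genes had a median of −0.34 over 28 members, of which 8 were at least 1.5-fold lower, with MVD at −1.03 and ACSS2 at −0.96, while the lipid carrier STARD4 stood at 1.19, and the list mean was −0.22. These 8 lists were outside both random ranges. The vehicle array's 3′ to 5′ signal, its lower 18S signal and its larger spread, which holds these gene differences, went with every list in this comparison.

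The largest remaining differences included genes of several kinds. SYBU, which links vesicles to kinesin, was higher by 3.05, the connexin gene GJA1 by 2.63, the potassium channel KCNK5 by 2.39 and OLR1, a receptor for oxidised lipoprotein, by 2.39. FAM83D was higher by 2.25, ANXA3 by 2.20, the phospholipase PLA2G4A by 2.16, NIPSNAP3B by 2.08 ± 0.37 (SD, n = 2), the Ras activator RASGRP1 by 1.99 and ANLN, needed for cytokinesis, by 1.99 ± 1.49 (SD, n = 2), or 3.05 without the probe sets open to cross-hybridisation. Lower were INHBE, an inhibin subunit, at −3.08, the secreted glycoprotein AZGP1 at −2.59, the metalloproteinase inhibitor TIMP1 at −2.36 and the folate receptor FOLR1 at −2.24 ± 0.86 (SD, n = 2).

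A further 7 lists were outside the range of random lists from all genes but inside that of lists drawn from the listed genes. Their medians were −0.20 for immediate early genes (mean −0.36), −0.25 for pro-apoptotic genes (mean −0.11), −0.19 for p53 targets, −0.18 for hypoxia and glycolysis, −0.15 for aryl hydrocarbon and oxidative stress genes, −0.14 for the mitochondrial respiratory chain (mean −0.06) and 0.22 for anti-apoptotic genes (mean 0.03). The means of pro-apoptotic genes, the mitochondrial respiratory chain and anti-apoptotic genes lay inside the central 95% of random-list means. Without the probe sets open to cross-hybridisation, anti-apoptotic genes (0.06) and the mitochondrial respiratory chain (−0.13) lay inside the range. With the median of a gene's probe sets, anti-apoptotic genes (0.17) and aryl hydrocarbon and oxidative stress genes (−0.14) did so, and ribosome biogenesis (−0.15) left it. Also inside the range from all genes were lists with medians of −0.12 for estrogen-repressed genes, −0.06 for nuclear receptors and cofactors, −0.08 for G1 to S genes, −0.11 for ribosome biogenesis, −0.03 for glucocorticoid, progestin and androgen responsive genes, −0.05 for growth factor signalling, −0.16 for luminal markers (mean −0.40), 0.06 for basal, stromal and blood cell markers and 0.01 for reference genes. The mean had the other sign for the nuclear receptors (0.05) and the glucocorticoid, progestin and androgen responsive genes (0.03). The means of growth factor signalling (−0.10, percentile 2.41) and of luminal markers (percentile 0) were outside the central 95% of random-list means. Estrogen-repressed genes lay outside, at −0.24, once the probe sets open to cross-hybridisation were left out.

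In the ERα17p array, the same lists of mitotic, histone, stress and NF-κB genes stood apart from the vehicle array, while the median of the estrogen-induced genes did not. ASPM was higher by 2.12 ± 0.80 (SD, n = 3), and CHAC1 and DDIT3 were lower, at −3.87 and −3.00. CYP1A1, a detoxifying enzyme induced through the aryl hydrocarbon receptor, was higher by 2.41, and NTN4, a secreted netrin, by 2.75. MYC stood at 0.38 and PGR at 0.88 ± 0.04 (SD, n = 2), while TFF1 was lower, at −2.92. Of the 19775 genes, 376 were at least 2-fold higher and 369 at least 2-fold lower.

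The 42 estrogen-induced genes had a median of −0.10 and a mean of −0.23, and the median lay inside both random ranges. The mean was at percentile 0.04 of the means of random lists from all genes, outside their central 95%. At least 1.5-fold lower were 10 members and higher 3. IGFBP4, which binds insulin-like growth factors, stood at −1.34, the chemokine gene CXCL12 at −1.33 ± 0.31 (SD, n = 2), SLC39A6 at 1.77 ± 1.03 (SD, n = 4), GREB1 at 0.24 ± 0.25 (SD, n = 3) and CCND1 at −0.04 ± 0.91 (SD, n = 2), or −0.69 without the probe sets open to cross-hybridisation. The G2 to M genes had a median of 0.61, with 18 members at least 1.5-fold higher and 1 lower. CDK1 was higher by 1.95 ± 1.02 (SD, n = 4) and CENPA by 1.90. The histone genes had a median of 0.44, with 3 of 9 at least 1.5-fold higher and 0 lower, and with H2BC4 at 1.75 and H4C8 at 1.01 ± 0.21 (SD, n = 2).

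Stress response genes had a median of −0.61, with 18 of 36 members at least 1.5-fold lower and 4 higher. SESN2 stood at −2.32 ± 0.23 (SD, n = 2) and the amino acid transporter subunit SLC3A2 at −2.03. NF-κB and inflammatory genes had a median of −0.64, with 16 of 31 at least 1.5-fold lower and 0 higher. CCL20 stood at −2.72, TNF at −2.47 and TNFAIP3 at −2.38 ± 0.37 (SD, n = 2). This median was −0.30 over the 23 members left without the probe sets open to cross-hybridisation. Immediate early genes, which serum and growth factors induce within minutes, had a median of −0.32, with 14 of 36 at least 1.5-fold lower and 3 higher. JUNB stood at −1.67, JUN at −1.46 ± 0.38 (SD, n = 4), IER2 at −1.36 and MAFF at −2.32 ± 2.39 (SD, n = 2). Ribosome biogenesis genes had a median of −0.27, with 6 of 38 at least 1.5-fold lower and 0 higher, among them RRP9 at −1.01 and BYSL at −0.90. These 6 lists were outside both random ranges, beside the same spread, 3′ to 5′ and 18S differences of the vehicle array as for estradiol.

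Among the other genes with the largest differences, ANXA3 was higher by 2.96, OLR1 by 2.74, SYBU by 2.39, the neuronal adhesion gene CNTN3 by 2.31, NIPSNAP3B by 2.30 ± 0.19 (SD, n = 2), FAM83D by 2.21, ANLN by 2.20 ± 1.196 (SD, n = 2), GJA1 by 2.11 and the cholinesterase gene BCHE by 2.09. Lower were INHBE at −2.97, AZGP1 at −2.57, TEX14 at −2.55, the neuropeptide gene NPW at −2.52 and TIMP1 at −2.35.

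By the range from all genes alone, 4 further lists stood apart from the vehicle array, with medians of 0.16 for heat shock, −0.29 for cholesterol and fatty acid synthesis, −0.20 for aryl hydrocarbon and oxidative stress and −0.22 for luminal markers. Without the probe sets open to cross-hybridisation, 3 of these lay inside the random range, heat shock at −0.04, aryl hydrocarbon and oxidative stress at −0.06 and luminal markers at −0.16. Among the remaining lists, medians were −0.01 for estrogen-repressed genes (mean 0.15), 0.06 for nuclear receptors, −0.10 for pro-apoptotic and 0.16 for anti-apoptotic genes, −0.09 for p53 targets and −0.09 for G1 to S genes. They were −0.07 for hypoxia and glycolysis, −0.04 for interferon response, 0.04 for glucocorticoid, progestin and androgen responsive genes (mean −0.01), −0.06 for growth factor signalling, 0.05 for basal, stromal and blood cell markers, −0.10 for the mitochondrial respiratory chain and 0.02 for reference genes. The means of hypoxia and glycolysis (−0.21, percentile 0.26) and of interferon response (−0.21, percentile 0.63) were outside the central 95% of random-list means, with 9 members at least 1.5-fold lower and 4 higher, and 11 lower and 3 higher. Without the probe sets open to cross-hybridisation, estrogen-repressed genes (0.18) and pro-apoptotic genes (−0.22) left the random range.

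**Figure D2:**
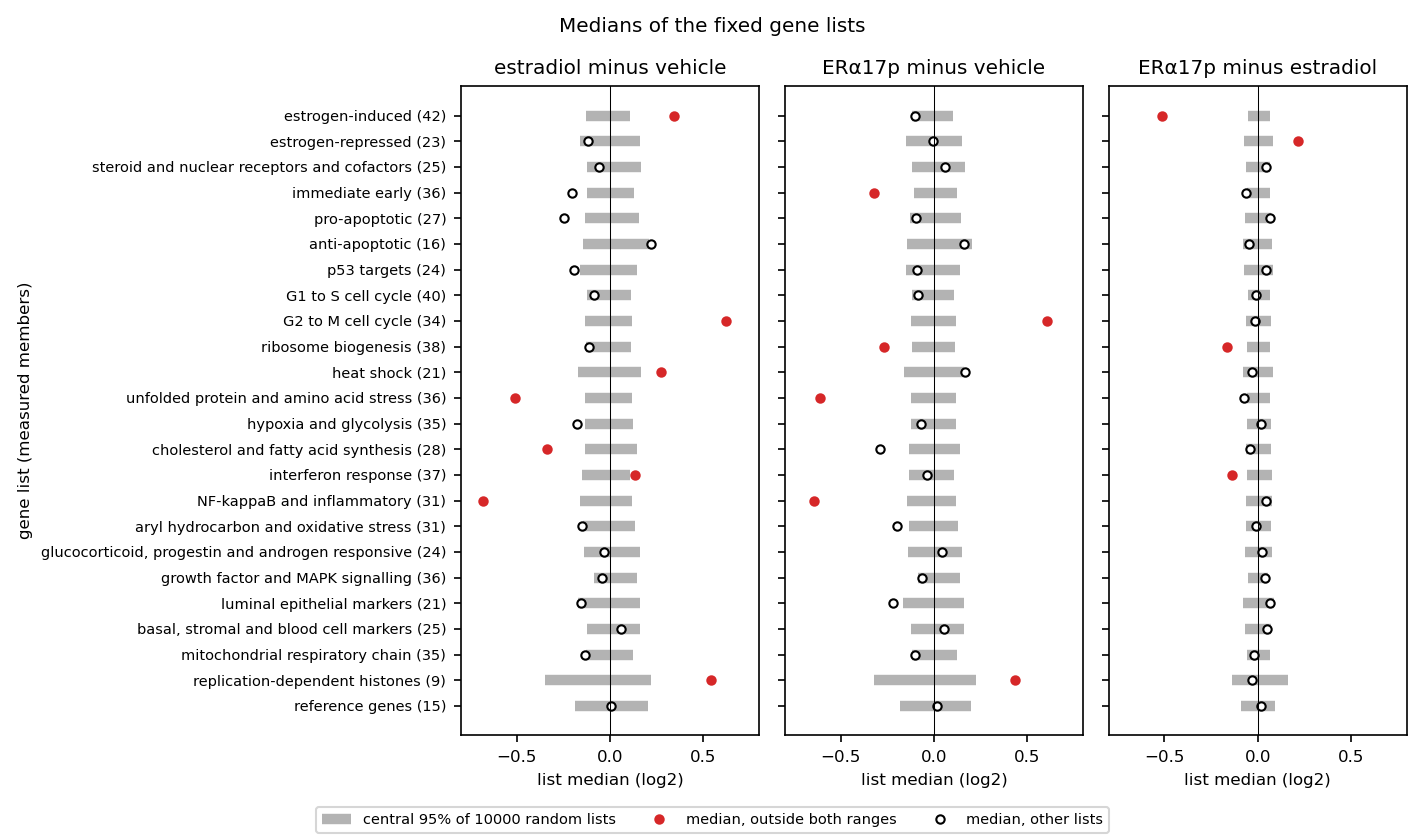
Median log2 difference of each of 24 gene lists in the 3 comparisons, with the number of measured members in brackets. Grey bars are the central 95% of 10000 random lists, filled points lie outside both random ranges, and estrogen-induced genes are at 0.34, −0.10 and −0.51 from left to right.

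Both treated arrays were compared for what they shared against the vehicle array. At least 2-fold higher in both were 244 genes, of 310 for estradiol and 376 for ERα17p, where independent lists would share 5.89. At least 2-fold lower in both were 231 genes, of 323 and 369, against 6.03. Only CXCL12 was 2-fold different in opposite directions, at 1.30 ± 0.36 (SD, n = 2) with estradiol and −1.33 ± 0.31 with ERα17p. Across genes, which are not independent replicates, Pearson's r between the differences was 0.897, Spearman's rank correlation was 0.848 and the covariance was 0.168. Simulated unchanged arrays of equal noise that share a vehicle gave 0.495, 0.475 and 0.0677. With the estradiol array as the common one, r was 0.169, and with the ERα17p array it was 0.284. In a further reference, added after the data were seen, the gene values of each array were shuffled across genes, which keeps the wider spread of the vehicle array. Over 100 shuffles the means were 0.883 for r, 0.816 for the rank correlation and 0.137 for the covariance, with 174 genes shared among the higher and 189 among the lower. The highest were 0.886, 0.821, 0.139, 186 and 212, so the observed values were above all shuffles. The shuffled arrays also gave fewer calls, on average 234 higher and 279 lower for estradiol, and 242 and 280 for ERα17p. The shared counts therefore do not compare lists of equal size. The shuffles keep the vehicle array's spread whatever its source, so they show only that a correlation of nearly this size and a large part of the overlap follow from it. A response shared by both treatments would be part of the same spread, and these values do not separate it from a property of the vehicle array. At least 2-fold above both other arrays were 231 genes for vehicle, 9 for estradiol and 5 for ERα17p, and 244, 3 and 4 genes were at least 2-fold below both.

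**Figure D3:**
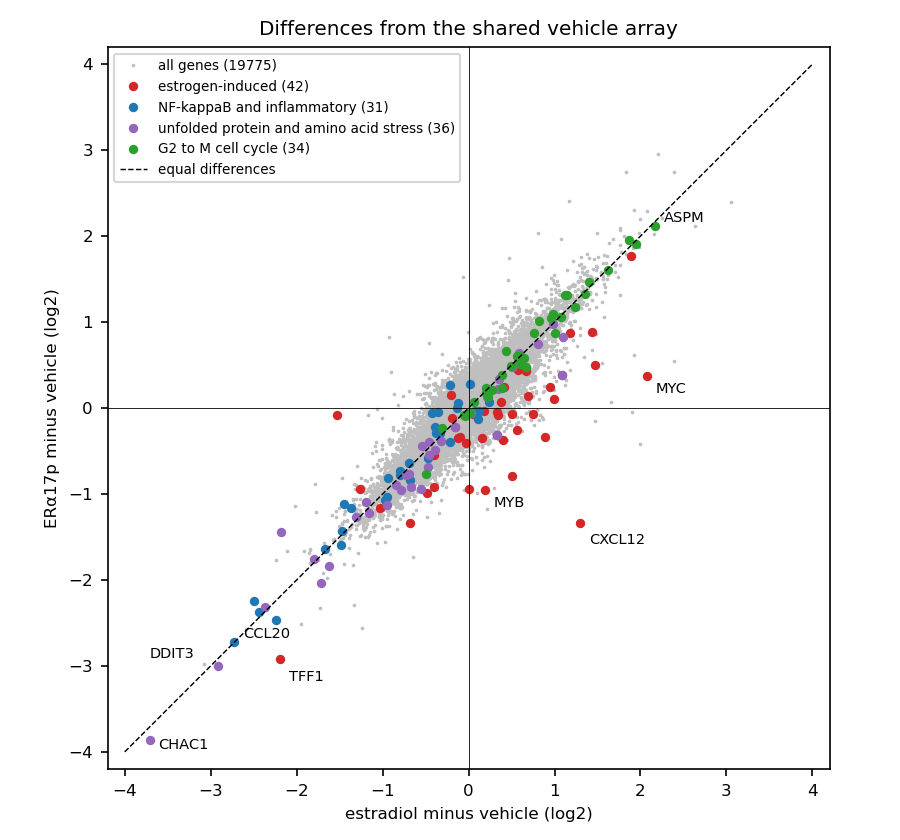
Difference of the ERα17p array from the vehicle array against that of the estradiol array, on log2 scales, with 1 point per gene (19775 genes) and 4 gene lists in colour. Most genes lie along the line of equal differences (r = 0.897), while MYC and CXCL12 lie below it.

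Set directly against the estradiol array, the ERα17p array had lower levels of estrogen-induced genes and higher levels of estrogen-repressed genes. CXCL12, whose product attracts cells that bear CXCR4, was lower, at −2.63 ± 0.67 (SD, n = 2), as were RASGRP1 at −2.41, the adrenergic receptor ADRA2A at −1.95, KCNK5 at −1.84, MYC at −1.70 and the kinase SGK1 at −1.63. Higher in the ERα17p array were SHISA2 by 1.75, the orphan nuclear receptor NR2F1 by 1.58, AMIGO2 by 1.44, the probe set named for mitochondrial COX3 by 1.33, LRIG3 by 1.27 and CYP1A1 by 1.23. This comparison does not use the vehicle array. It had 12 genes at least 2-fold higher and 17 at least 2-fold lower.

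The 42 estrogen-induced genes had a median of −0.51, below both random ranges (−0.05 to 0.07 from all genes and −0.07 to 0.05 from the listed genes). Of these, 38 lay below 0, 16 were at least 1.5-fold lower and 1, AMIGO2, was at least 1.5-fold higher. NPY1R, a receptor for neuropeptide Y, stood at −1.30, TFF1 at −0.74, GREB1 at −0.70 ± 0.60 (SD, n = 3), PGR at −0.55 ± 0.24 (SD, n = 2) and CCND1 at −0.37 ± 0.08 (SD, n = 2). The 23 estrogen-repressed genes had a median of 0.22 (random lists −0.07 to 0.08), with 17 above 0, 4 at least 1.5-fold higher and 0 lower. Besides CYP1A1, these were BCAS1 at 0.63, CCNG2, an inhibitory cyclin, at 0.61 ± 0.39 (SD, n = 5), and LIPH at 0.61 ± 0.03 (SD, n = 2).

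**Figure D4:**
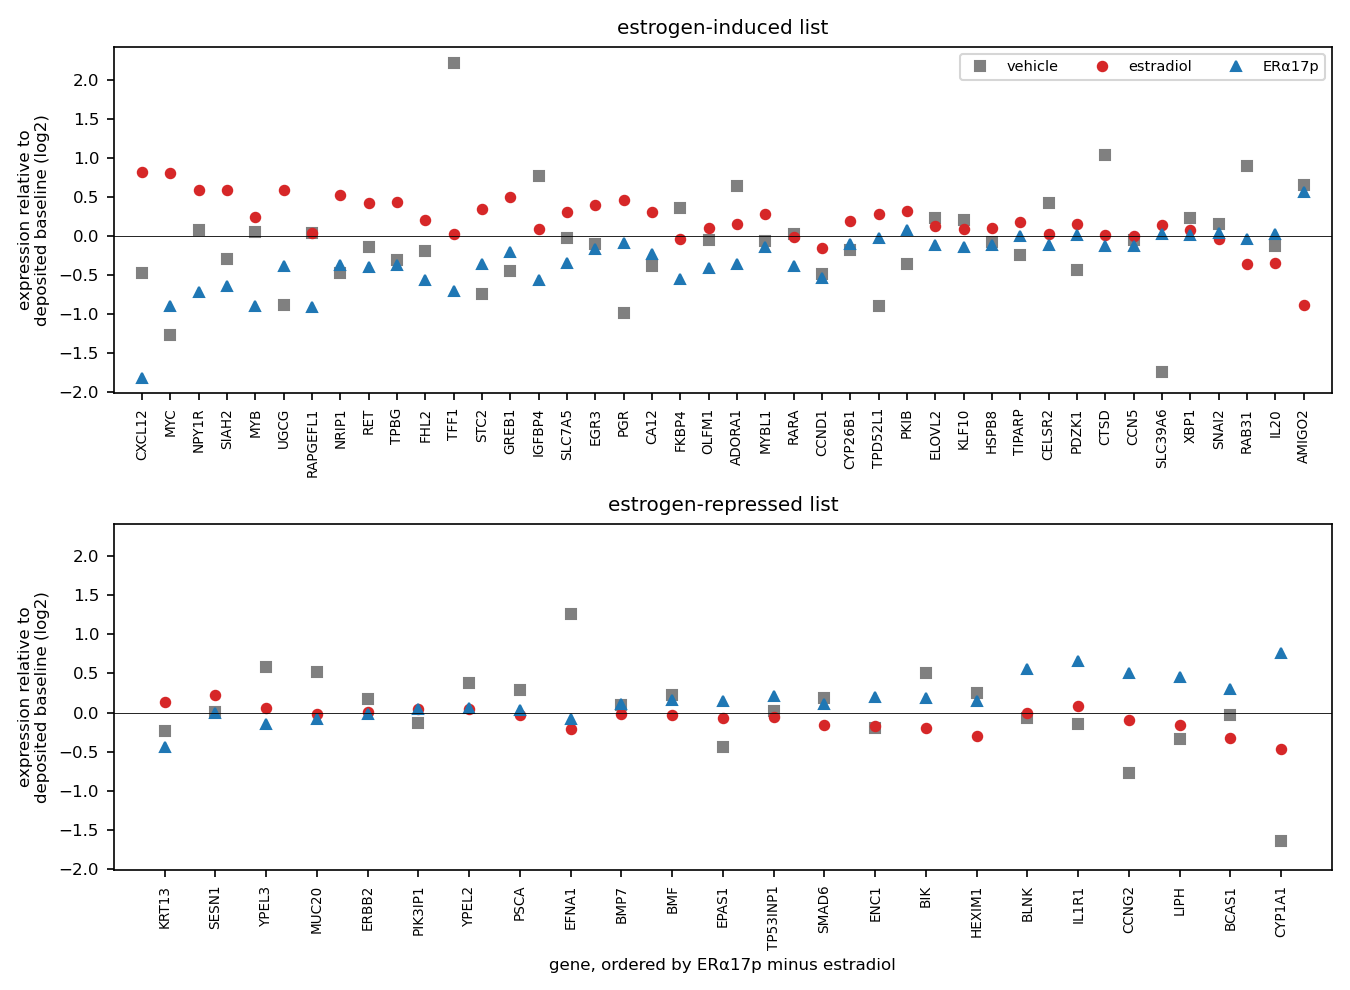
Level of each estrogen-induced gene (42, upper panel) and estrogen-repressed gene (23, lower panel) on the vehicle, estradiol and ERα17p arrays, on the log2 scale relative to the deposited baseline, ordered by ERα17p minus estradiol. In the upper panel 38 of 42 genes are lower on the ERα17p than on the estradiol array, and in the lower panel 17 of 23 are higher.

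Ribosome biogenesis genes had a median of −0.17 in the ERα17p array relative to estradiol, with 32 of 38 below 0 and 0 at least 1.5-fold different. RRS1 stood at −0.50, PPRC1 at −0.43, POLR1C at −0.35 ± 0.11 (SD, n = 2) and MRTO4 at −0.32 ± 0.01 (SD, n = 2). Interferon response genes had a median of −0.14, with 27 of 37 below 0 and 1, IFI27 at −0.87, at least 1.5-fold lower. HERC5 stood at −0.58, RSAD2 at −0.52 ± 0.34 (SD, n = 2) and ISG15 at −0.49. Both lists were outside both random ranges. Immediate early genes (−0.06) and stress response genes (−0.07) were below the range from all genes alone. Without the probe sets open to cross-hybridisation, immediate early genes stood at −0.0044 over 27 members, inside their random range. Stress response genes changed little, to −0.0619 over 26 members. They lay inside the wider range for that size (−0.0773 to 0.0911), but below that for all 36 members (−0.0592 to 0.0683).

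Apart from the stress response genes, the lists that stood farthest from the vehicle array in both treated arrays differed little between these arrays. The median was −0.02 for G2 to M genes, −0.03 for histones and 0.05 for NF-κB and inflammatory genes, all inside the random ranges. Also inside were nuclear receptors (0.04), anti-apoptotic genes (−0.05, mean 0.0008), p53 targets (0.05), G1 to S genes (−0.01, mean 0.03), heat shock (−0.03), hypoxia and glycolysis (0.02), cholesterol and fatty acid synthesis (−0.04) and aryl hydrocarbon and oxidative stress genes (−0.01, mean 0.03). The remaining medians were 0.02 for glucocorticoid, progestin and androgen responsive genes (mean −0.04), 0.04 for growth factor signalling, 0.06 for luminal markers, 0.05 for basal, stromal and blood cell markers, −0.02 for the mitochondrial respiratory chain and 0.02 for reference genes. The means of growth factor signalling (0.07, percentile 99.6) and of pro-apoptotic genes (0.08, percentile 98.5) were outside the central 95% of random-list means. Pro-apoptotic genes, at a median of 0.07, lay inside the range from all genes and above that from the listed genes (−0.09 to 0.06). They left the range from all genes, at 0.11, without the probe sets open to cross-hybridisation, and at 0.10 with the median of a gene's probe sets.

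The receptors themselves differed little among the 3 arrays. ESR1, the gene of estrogen receptor α, differed from vehicle by 0.10 ± 0.20 (SD, n = 9) in the estradiol array and 0.18 ± 0.24 in the ERα17p array. ESR2 differed by −0.07 ± 0.28 (SD, n = 6) and −0.15 ± 0.14, and the membrane estrogen receptor gene GPER1 by 0.07 ± 0.37 (SD, n = 2) and −0.08 ± 0.09. Between the ERα17p and estradiol arrays the differences were 0.08 ± 0.25 for ESR1, −0.07 ± 0.19 for ESR2 and −0.15 ± 0.28 for GPER1.

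Probe sets of a gene came nearest to a repeat measurement. Of 673 genes with a first probe set at least 2-fold different between estradiol and vehicle, 37.4% had a second set at least 1.5-fold different the same way, against 21.7% after shuffling second sets. For ERα17p and vehicle it was 39.6% of 718 genes against 21.2%, and for ERα17p and estradiol 43.5% of 23 genes against 17.4%. Many of the named differences rest on 1 probe set, and no difference has a replicate check.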

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

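Of the tests in this part, the correlation between probe sets was chosen only after the vehicle array had been seen to stand apart.

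Of 6 control probe sets for ribosomal RNA, which belong to no comparison, 4 differed at least 2-fold between the vehicle array and both treated arrays. The mean of both treated arrays exceeded the vehicle array by 1.41 for the 3′ set of 18S RNA, 1.93 for its 5′ set, 2.10 for its middle set and 1.94 for the 5′ set of 28S RNA, on the log2 scale. The other 28S sets differed little, by 0.09 and 0.29 for the 3′ set and −0.02 and −0.22 for the middle set with estradiol and ERα17p. Probe sets without a single gene name also held differences. Of 13522 such sets, 601 differed at least 2-fold between estradiol and vehicle (212 higher, 389 lower), 786 between ERα17p and vehicle (212 higher, 574 lower) and 16 between ERα17p and estradiol (1 higher, 15 lower).

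The vehicle array stood apart from both treated arrays in the gene counts and in most of these controls. Random noise of single probe sets as the only source is argued against, since a pair of probe sets of a gene moved together. For vehicle minus the mean of the treated arrays, r was 0.368 (95% bootstrap range 0.349 to 0.386 over 10523 genes). An r of this size leaves room for such noise as a part of the differences. RNA integrity or labelling of the vehicle array could contribute, as it would move probe sets of a gene apart even in genes with no mean difference. In 2981 such genes, with a mean within 0.1 of 0, the median within-gene SD was 0.186 for vehicle against treated. Between the treated arrays it was 0.154, over a separately chosen set of genes with a mean within 0.1 of 0 in that comparison. The ratio was 1.21 (range 1.17 to 1.27). This was above the 0.866 of equal noise and above the 0.95 that would have argued against the explanation, so it leaned toward it, but its range did not clear the limit of 1.2 set for this test. With 1 vehicle culture, a response shared by both treatments and a property of that culture or its RNA cannot be told apart.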

How the results depend on the processing

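The requirement that every probe set of a gene pass the threshold, the median of a gene's probe sets, the random lists from listed genes and the left-out vehicle array were chosen after seeing the data. No paired analysis was possible because each group had 1 array. The counts for genes higher and lower depended on the threshold. At 1.5-fold they were 1281 and 1665 for estradiol minus vehicle, 1361 and 1732 for ERα17p minus vehicle, and 103 and 120 for ERα17p minus estradiol. At 3-fold they were 44 and 35, 57 and 38, and 1 and 6. Where a gene had at least 2 probe sets and each passed 2-fold, they were 20 and 33, 37 and 40, and 1 and 3, a rule that leaves fewer genes to count. With the vehicle array left out and the other treated array as the reference, counts were 17 and 12 for estradiol and 12 and 17 for ERα17p. The correlation of the differences from vehicle was 0.877 without probe sets open to cross-hybridisation, 0.891 over probe sets and 0.889 with the median of a gene's probe sets, each further from the main value than its bootstrap SD of 0.0025. Without the probe sets open to cross-hybridisation, the 15 heat shock genes left of 21 had medians of −0.0847 for estradiol and −0.036 for ERα17p minus vehicle. Taking the mean of members, with all probe sets kept, turned interferon response genes to −0.0539 for estradiol minus vehicle; the cause was not tested. Of 18 list medians outside both random ranges, 16 stayed outside on the same side without those probe sets and 17 with the median of a gene's probe sets. Of all 75 list medians, leaving out the probe sets open to cross-hybridisation moved 30 by at least the SD of their random lists and left 43 within it. It turned the sign of 2 that had been outside the range from all genes. The mean of members moved 29 and turned 1, and the median of a gene's probe sets moved 10 and turned 0. For named differences the limit was the pooled SD of probe sets within a gene, 0.371. Leaving out those probe sets moved 5 past it and left 57 within it, and the remaining ones of the 80 had no probe set left. Centring moved 0 of 75 list medians and 0 of 80 named differences, but it shifted them by only −0.0043, 0.0011 and 0.0062. Unmatched random lists moved 2 of 75 lists across a limit, and lists drawn from the listed genes moved 14. Agreement of probe sets by direction alone was 76.7%, 77.7% and 87.0%. A floor at the 75th percentile, cyclic loess and the pseudocount of 32 were not run, and signal over background is unknown, because the values keep no absolute level.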

Other observations

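Of the tests in this part, those of a response of the estradiol culture, of the state of the vehicle culture, of the number of members below 0, of members with at least 2 probe sets and of lists matched on the vehicle axis were chosen only after the results were seen.

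Some genes were at least 2-fold above or below both other arrays in the peptide array or the hormone array, as counted in the report and named here after their values were seen. At least 2-fold above both other arrays with ERα17p were CYP1A1, NR2F1, LRIG3, FLRT3 and DKK1. CYP1A1 was also higher than vehicle with estradiol, by 1.17. DKK1, a secreted Wnt inhibitor, was higher than vehicle by 1.49 with ERα17p and 0.46 with estradiol, and FLRT3, an adhesion protein, by 2.04 and 0.81. Below both others with ERα17p were CXCL12, TEX14, ELOVL2-AS1 and HEY2, a Notch target that stood at −1.18 against vehicle and −1.40 against estradiol. TEX14 was also lower than vehicle with estradiol, at −1.24, and CXCL12 is named for both arrays, in opposite directions. With estradiol, ADRA2A, KCTD6, RBM24, ZSWIM6, CXCL12, KCNK5, MYC, RASGRP1 and SGK1 were above both others, KCTD6 by 1.92 against vehicle. AMIGO2, GNAI1 and PLK2 were below both others, and PLK2, a polo-like kinase, stood at −1.17 against vehicle.

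Further members of lists are named here after their values were seen. In the growth factor list, whose median against vehicle was −0.05 with estradiol and −0.06 with ERα17p, inside both random ranges (mean −0.10 with estradiol, percentile 2.41), DUSP5 stood at −1.77 and −1.204, DUSP4 at −1.47 ± 0.44 (SD, n = 3) and −0.81 ± 0.20, and DUSP6 at −1.01 ± 0.98 (SD, n = 3) and −0.12 ± 0.78. In the pro-apoptotic list, with medians of −0.25 and −0.10, FAS was higher than vehicle by 1.61 ± 0.92 (SD, n = 5) and 1.77 ± 0.88, while PMAIP1 stood at −1.22 ± 1.28 (SD, n = 2) and −1.41 ± 0.94, and BAK1 at −0.85 and −0.75. The death ligand gene TNFSF10 was higher with ERα17p than with estradiol by 0.55 ± 0.03 (SD, n = 3). The hypoxia and glycolysis list had medians of −0.18 and −0.07, with 16 and 13 of 35 members above 0. In it the glycolytic genes ENO2 and ALDOC were lower with estradiol, at −1.69 and −1.68, and with ERα17p, at −1.92 and −1.56. The pioneer factor FOXA1 was higher with ERα17p than with estradiol by 0.50 ± 0.05 (SD, n = 2). Its lists, nuclear receptors and luminal markers, had medians of 0.04 and 0.06 there, inside both random ranges.

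Lower estrogen-induced and higher estrogen-repressed genes in the ERα17p than in the estradiol array may reflect a response of the estradiol culture to the hormone that the peptide culture lacked. Probe noise is argued against for the induced genes, since 38 of 42 lay below 0 (random lists 14 to 27), whereas the least moved probe set did not decide, at −0.271 over all members, of which those with 1 probe set could not move, and −0.266 over the 25 others, whose bootstrap range of −0.383 to −0.0227 reached into that of random lists (−0.038 to 0.0428). The axis that sets the vehicle array apart was almost unrelated across genes to the difference between the treated arrays (slope −0.0291, r = −0.0624). Removing it by regression could therefore move little and decides nothing, at −0.494 for the induced and 0.204 for the repressed genes. Genes matched on this axis (−0.0495 to 0.0692) did not share the difference of the induced genes, at −0.511 (bootstrap range −0.650 to −0.271). That list lay near 0 on the axis, at a median of −0.0126, so matching tested little. For the repressed genes the axis stays open, at 0.218 (0.0594 to 0.384) against matched lists of −0.07 to 0.0882. Against vehicle in the estradiol array, as the hypothesis needs, induced genes were higher, at 0.342 (percentile 100) or 0.16 without the probe sets open to cross-hybridisation, although both comparisons share that array and TFF1 stood at −2.19, while repressed genes, at −0.12 (percentile 7.39), were inside both random ranges. Lower levels in the peptide culture itself stay open, since against vehicle the induced genes had a mean of −0.23 there (percentile 0.04) with 28 of 42 below 0, although the median of −0.10 was inside the random ranges, as does an untested property of either single culture.

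NF-κB and stress response genes, 67 in both lists together, were lower in both treated arrays than in the vehicle array, at a median of −0.578. With the least moved probe set of each gene the median was −0.240, but genes with 1 probe set could not move in that test. Over the 42 members with at least 2 probe sets it was −0.077, against −0.390 with the mean of their probe sets, and although random lists gave −0.0493 to 0.0509, its bootstrap range of −0.203 to 0.0649 reached into theirs. RNA integrity or labelling of the vehicle array therefore stays open for these lists. The median between both treated arrays was −0.0464 (percentile 1.6), just below the range of random lists (−0.0425 to 0.0514) but far smaller in size than −0.578. The state of the single vehicle culture, which may have been stressed, and a response shared by both treatments cannot be told apart. Each predicts only that the treated arrays differ far less from each other than from the vehicle array.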
